A study of Mus musculus with 21 samples.

How the data were processed

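Bulk RNA sequencing was analysed from 21 libraries of mouse CD4 T cells, 3 for each of 7 groups. Per the labels, naive cells low for CD44 and negative for CD25 were sorted from spleen and lymph nodes of mice heterozygous for an eGFP reporter in the Il23r locus, and were cultured for 5 days on plates coated with antibodies against CD3 and CD28. Cytokines were IL-12 at 20 ng/ml, IL-12 with IL-21 at 20 ng/ml each, IL-1b at 20 with IL-6 at 25 and IL-23 at 20 ng/ml, or TGF-b at 2 with IL-6 at 25 ng/ml. The cells were then sorted by eGFP fluorescence, and libraries were made with SMART-Seq2, which amplifies full-length cDNA from small numbers of cells. The culture with IL-12 alone was represented by GFPneg cells, and each of the other cultures by GFPpos and GFPneg cells.

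The values were TPM (transcript abundance scaled to a fixed library total), deposited by the authors as 1 table of 23415 gene symbols. Per the submitters' processing notes, Trimmomatic 0.32, Bowtie2 2.2.9, RSEM 1.2.31 and the genome build GRCm38 were used. Their order and settings, the gene annotation, any filter and the use of strand were not given in the sources used here. The values of each library summed to the same total, so the number of reads behind a value was unknown and no counting interval could be given. As TPM keeps no depth, the number of genes above 0 was used as a description of each library. A value of exactly 0 can be a failed estimate, so such genes are described as listed at 0. TPM values are shares of a library, so a rise of some transcripts lowers all others. Overlapping genes, antisense genes and close copies such as Il22 with Iltifb, Ctla2a with Ctla2b and the H2-Q genes may share reads, and their separate values are uncertain.

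Columns were tied to samples by their names, and 0 columns lacked a sample. Of the symbols, which the table gives in capitals, 22434 matched GENCODE M21, 441 matched through RefSeq synonyms and 540 stayed unmatched; 8192 genes had no value above 0 in any library. The row EGFP_IRES_IL23R, a sequence of the reporter, may share reads with Il23r. Rows whose names begin with TRN, and the rows TDTOMATO and ICRE, are named as in the table, which does not say what they hold.

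Tests used limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with group means and no block, empirical Bayes with a trend, and Benjamini-Hochberg adjustment within each comparison. Fold changes are therefore on the log2(TPM + 1) scale, which understates changes of low genes. Genes with a TPM of at least 1 in at least 3 libraries were tested, 9657 in the fit of all 21 libraries, and an adjusted p under 0.05 was the threshold. All groups shared 1 estimate of the spread. There were 7 comparisons and 3 interactions, each a difference of the GFP effect between cultures. Exact tests of 3 against 3 cannot go below a two-sided p of 0.1. Nothing in the labels says that replicates came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

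Gene lists were tested with camera, a competitive gene set test of limma, at a preset correlation of 0.01 between genes, adjusted over 161 tests, and again with the correlation estimated by camera. The 26 lists were the Th1 program, Th17 program, pathogenic Th17 signature, non-pathogenic Th17 signature, Th2 program, regulatory T cell program, follicular helper program, naive and central memory genes, cytotoxic and natural killer receptor genes, co-inhibitory receptors and regulators, interferon-stimulated genes, proliferation genes, glycolysis genes, cholesterol synthesis genes, TGF-beta response genes, JAK-STAT feedback and STAT3 target genes, cytokine receptor genes, immediate early and T cell receptor response genes, heat shock genes, mitochondrially encoded genes, and markers of B cells, of myeloid and dendritic cells, of natural killer cells, of CD8 T cells, of gamma-delta and innate-like T cells, and of erythroid cells and neutrophils. Some genes stand in more than 1 list.

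Genes were named by a rule. It took genes with an adjusted p under 0.05, an absolute log2 change of at least 1, no overlap between the replicates of both groups, a mean TPM of at least 5 in the higher group and no predicted-gene or receptor-segment symbol, and from these the 10 largest rises and 10 largest falls. It added up to 4 members of each list with the smallest adjusted p, and in every comparison a fixed set that included Il23r, Ifng, Tbx21, Il17a, Il17f, Il21, Il10, Csf2, Il22, Foxp3, Gata3, Maf and Cd160. The groups, the tests, the lists, the naming rule and the first set of alternatives were chosen before the data were examined. These alternatives were pseudocounts of 0.1 and 5, no filter or a minimum of 5 TPM, quantile or median-ratio scaling, only the libraries compared, the replicate number as a block, array weights, no trend, an estimated correlation for the lists, and each library left out in turn.

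The remaining choices were made after seeing the data, when 5 libraries stood apart from the other 16. Fits were added without the 3 libraries that had fewer than 5000 genes above 0 (18 libraries, 9649 genes), and without these and the 2 further libraries whose median correlation with the others was under 0.85 (16 libraries, 9592 genes), with and without median-ratio scaling and the block. The naming rule was repeated on the fit of 16 libraries with the same exceptions. Il23r and the reporter row were left out where called genes were compared between the GFP comparisons. That fit left 1 GFPpos library of TGF-b with IL-6, which was assumed to vary like the other groups.

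Both fits were tested on simulated data with changes of 1, 2 or 3 on the log2 scale in 67, 67 and 66 genes. These genes were drawn from those with a mean log2(TPM + 1) of at least 3 in the 16 libraries. Each simulated library had the same normal spread for a gene, and all groups had the same mean before the changes. In simulations of the GFP comparison in IL-1b with IL-6 and IL-23, of IL-12 with IL-21 against that culture, and of IL-12 with IL-21 against TGF-b with IL-6, the fit of 21 libraries (9657 genes) recovered 0% of the genes at each size, with 0 false calls. For the first of these, the fit of 16 libraries (9592 genes) recovered 64.2%, 98.5% and 98.5% at the 3 sizes, with 7 false calls. For the next it recovered 59.7%, 100% and 97%, with 5 false calls, and for the last 32.8%, 88.1% and 95.5%, with 9 false calls. These rates hold for that setting only, since in the data 5 libraries stood apart from the other 16. With the real data the fit of 21 libraries called 32 and 53 genes in the last 2 of these comparisons. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.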

Results

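RNA was measured in CD4 T cells of reporter mice after 5 days in cytokine cultures that lead naive cells toward different effector types. IL-12 favours Th1 cells, which make interferon gamma, and IL-6 with TGF-b, or with IL-1b and IL-23, favours Th17 cells, which make IL-17. The reporter allele places eGFP behind the gene of the IL-23 receptor, Il23r, and makes no working receptor, so GFPpos cells are those that transcribe the locus. The series is about Th1-like cells, the IL-23 receptor and colitis. The cultures ask which transcripts accompany reporter activity in each culture, and how cells with an active reporter differ between cultures. There were 3 libraries in each of 7 groups, of which IL-12 alone had GFPneg cells and the other cultures, here IL-12+IL-21, IL-1b+IL-6+IL-23 and TGFb+IL-6, had both sorts.

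The genes that mark the cultures, with their places in GRCm38 (GENCODE M21), are all protein-coding. Il23r lies on the minus strand of chromosome 6 from 67422932 to 67491855. Ifng lies on the plus strand of chromosome 10 from 118441046 to 118445892, and Il22 on the same chromosome and strand from 118204942 to 118210047. Il17a lies on chromosome 1 from 20730905 to 20734496 (plus) and its neighbour Il17f from 20777146 to 20790617 (minus). Il21 lies on chromosome 3 from 37222759 to 37232636 (minus) and Tbx21 on chromosome 11 from 97098071 to 97115331 (minus).

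The libraries differed in quality. In 16 of the 21, between 10384 and 12610 genes lay above 0 and the median correlation with the other libraries was 0.919 to 0.95. The library labelled TGFb+IL-6 GFPneg replicate 3 had 191 genes above 0, TGFb+IL-6 GFPpos replicate 3 had 1157 and IL-12+IL-21 GFPneg replicate 3 had 1331. IL-12 GFPneg replicate 1 (7512 genes, correlation 0.748) and TGFb+IL-6 GFPpos replicate 2 (10477 genes, correlation 0.787) had 53.7% and 56.9% of their TPM in ribosomal protein genes, against 31.7% to 42.6% in the 16, and 12.5% and 10.8% in Rpl41 alone, against 1.91% to 2.84%. Comparisons below give the number of genes called with all 21 libraries, and then values from the 16 libraries, a choice made after these differences were seen. Unless stated otherwise, folds and adjusted p-values are limma's with 16 libraries, errors of log2 changes are SE, and TPM levels are mean ± SD over the libraries among the 16. TGFb+IL-6 GFPpos is then a single library, replicate 1, with no SD of its own.

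**Figure D1:**
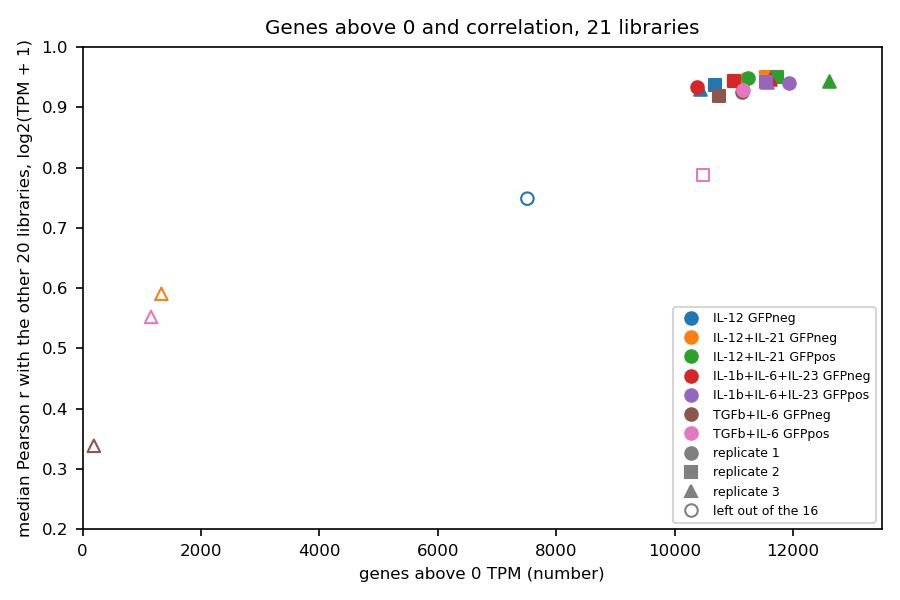
Genes above 0 TPM (x axis, number) against the median Pearson correlation of log2(TPM + 1) with the other 20 libraries (y axis), 1 point per library, coloured by group and shaped by replicate number. The 16 filled points lie between 10384 and 12610 genes, and the 5 open points, at 191 to 10477 genes, have correlations of 0.338 to 0.787.

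Il23r and the reporter, the sorting marker, were checked first and are no finding. Il23r was at 31.8, 24.2 and 36.4 TPM in IL-12+IL-21 GFPpos and at 3.04, 6.36 and 0 in GFPneg replicates 1 to 3. In IL-1b+IL-6+IL-23 it was at 21.7, 24.9 and 38.9 TPM in GFPpos and at 7.33, 6.02 and 7.56 in GFPneg. In TGFb+IL-6 it was at 3.57, 1.69 and 146 TPM in GFPpos and at 0.87, 0.73 and 0 in GFPneg, where the value of 146 belongs to the library with 1157 genes. In IL-12 GFPneg it was at 0, 1.5 and 0. The row EGFP_IRES_IL23R was at 27, 23.3 and 35 TPM in IL-12+IL-21 GFPpos, at 21.2, 17.4 and 32.3 in IL-1b+IL-6+IL-23 GFPpos, at 9.64, 0 and 0 in TGFb+IL-6 GFPpos, and at 0 to 5.29 in the GFPneg libraries. The sort and the transcript thus went the same way in most libraries. The exceptions were TGFb+IL-6 GFPpos replicates 2 and 3, with the reporter row listed at 0.

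**Figure D2:**
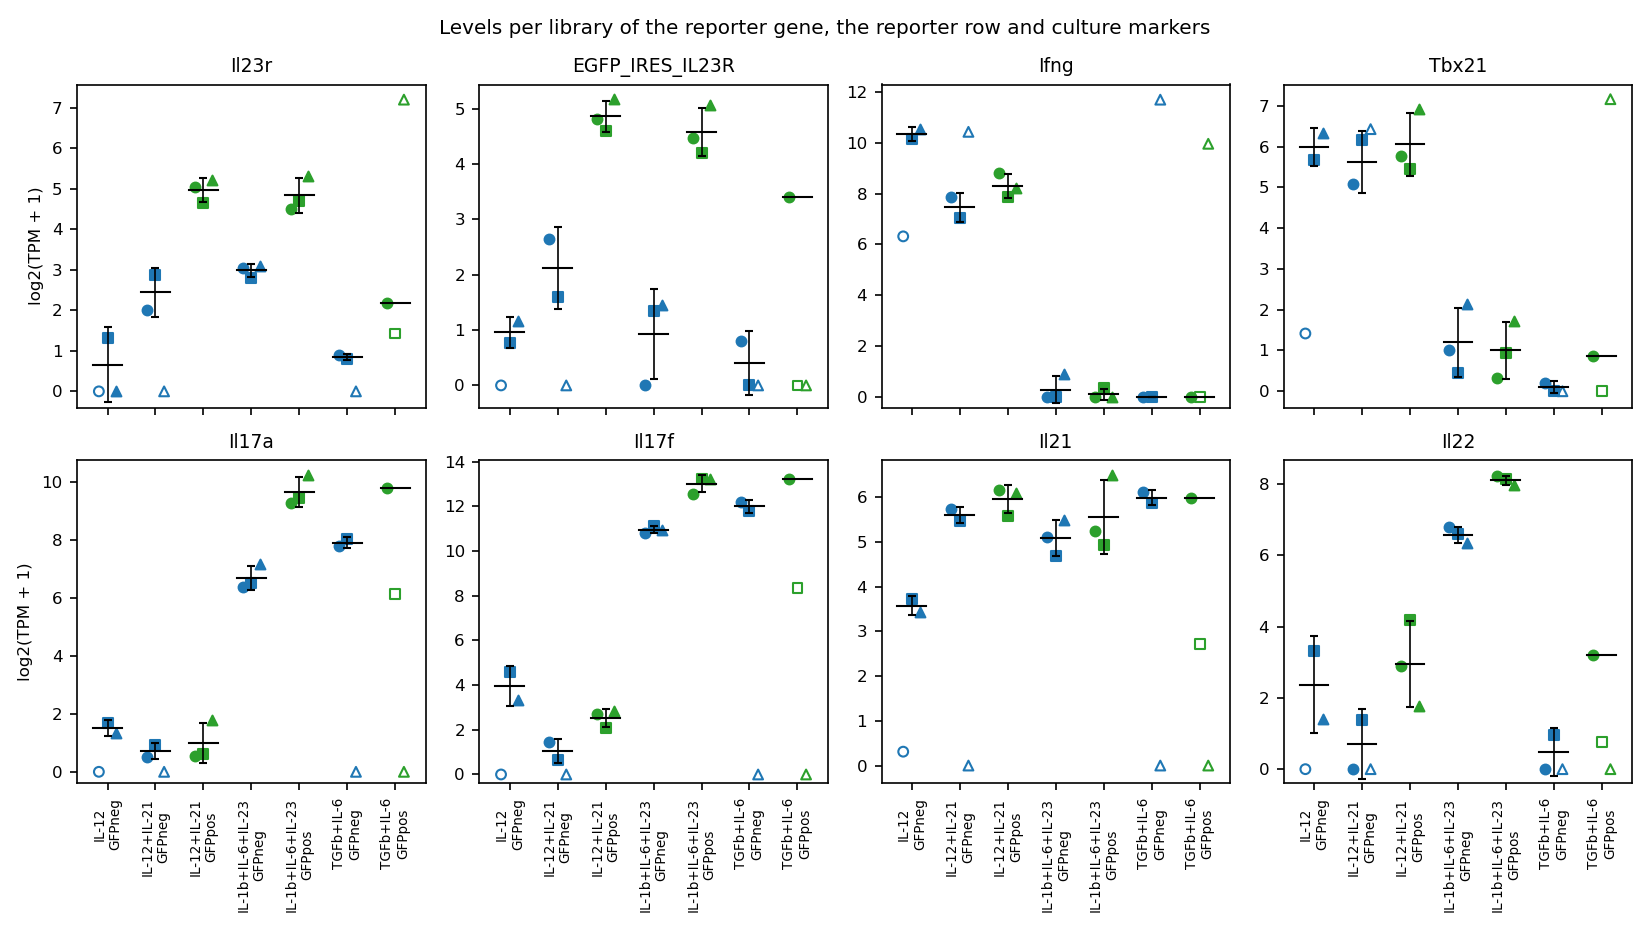
Levels of Il23r, the reporter row and 6 culture marker genes as log2(TPM + 1) (y axes) in each library of the 7 groups (x axes), GFPneg in blue and GFPpos in green, with replicates 1, 2 and 3 as circle, square and triangle. Bars are mean ± SD of the log2 values over the filled points; open points are the libraries outside the 16, such as the TGFb+IL-6 GFPpos triangle with Il23r at 146 TPM.

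In IL-12+IL-21, few genes were called between GFPpos and GFPneg cells. By limma with 16 libraries 1392 of 9592 genes had an unadjusted p under 0.05, so few calls do not mean few differences. Besides Il23r, Cxcr1, a chemokine receptor gene, rose by 2.11 ± 0.36 on the log2 scale, from 2.16 ± 1.78 to 11.6 ± 1.78 TPM (n = 2 and 3, adjusted p = 0.0264). Ppp1r14b rose by 1.69 ± 0.24, Smpdl3a by 1.39 ± 0.24 and Dcxr by 1.14 ± 0.21. Hmgb2, which encodes a chromatin protein, fell from 92.2 ± 7.81 to 36.5 ± 5.45 TPM, Hmgn2 from 107 ± 0.757 to 43.4 ± 5.26 and the histone variant gene H2afz from 1187 ± 93.5 to 552 ± 42.9 TPM (adjusted p = 0.0139 each). Hmgn2 changed by 0.97 with all 21 libraries (adjusted p = 0.72). The Th1 genes Ifng, at 328 ± 111 TPM in GFPpos and 181 ± 70.1 in GFPneg (adjusted p = 0.261), and Tbx21, which encodes the Th1 regulator T-bet, at 72.7 ± 42.5 and 51.8 ± 26.8 (adjusted p = 0.729), did not pass. Neither did the Th17 cytokine genes Il17f (4.96 ± 1.53 and 1.15 ± 0.785 TPM; adjusted p = 0.0841) and Il22 (8.75 ± 7.67 and 0.81 ± 1.15 TPM; adjusted p = 0.115).

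By list, proliferation genes had a median above 0 by GFP status in IL-12+IL-21 with all 21 libraries, below the 0.938 of all genes. With 16 libraries they were lower in GFPpos cells. None of 18 members passed over all genes and 6 fell when adjusted over the list alone, with a median of -0.60 (camera adjusted p = 7.15e-17, and adjusted p = 0.0676 with an estimated correlation). Heat shock genes had a median of -0.465, 0 of 7 passing and 4 falling adjusted over the list alone (adjusted p = 7.69e-08, and adjusted p = 0.0801 with an estimated correlation). Cholesterol synthesis genes had a median of 0.50 with 4 of 20 rising adjusted over the list alone (adjusted p = 0.00111; 0.488 with an estimated correlation), co-inhibitory receptors and regulators 0.65 with 2 of 9 (0.013; 0.423), and the Th17 program 0.52 with 3 of 15 (0.0399; 0.444). Median-ratio scaling lowered these medians to 0.219, 0.365 and 0.266. Glycolysis genes (median -0.08; adjusted p = 0.0135) and interferon-stimulated genes (median -0.01; adjusted p = 0.0244) ranked low without a member passing, had medians of -0.368 and -0.298 with that scaling, under which heat shock genes had -0.752, and lost the call with an estimated correlation (adjusted p = 0.64 and 0.444). Erythroid and neutrophil markers came down to 1 tested gene, Csf3r, which was not called itself (-0.73, adjusted p = 0.217, and 0.29 with 21 libraries). The camera call of this list (adjusted p = 0.0212, and adjusted p = 0.169 with an estimated correlation) thus rests on a single gene that did not pass. Over all genes 15 were called, 11 higher and 4 lower in GFPpos, against 8 with median-ratio scaling, 2 higher and 6 lower, which moved the median of all genes from 0.244 to 0.0132. Cxcr1, Smpdl3a, Dcxr and H2afz were not called with that scaling (adjusted p = 0.0752, 0.0737, 0.0756 and 0.0586), while no named gene or called list changed direction. Without IL-12+IL-21 GFPneg replicate 1 no gene was called, and without GFPneg replicate 2 or GFPpos replicate 1, 2 or 3 there were 3, 2, 3 and 2. All 21 libraries gave 6 genes, all higher in GFPpos, including Cxcr1, Calca (3.24, adjusted p = 0.0338) and the row TRNT (adjusted p = 0.00898). TRNT was at 343 ± 134 TPM in GFPpos and listed at 0 in GFPneg. Of the 6, 1 was also called with 16 libraries, while Calca (adjusted p = 0.0561) and TRNT (adjusted p = 0.161) were not. With 18 libraries limma called 0, with 204 genes at an unadjusted p under 0.05.

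In IL-1b+IL-6+IL-23, GFPpos cells carried more transcript of the IL-17 genes than GFPneg cells. Il17a rose by 2.97 ± 0.33, from 104 ± 32.6 to 837 ± 316 TPM (n = 3 and 3; adjusted p = 0.000649), and Il17f by 2.05 ± 0.30, from 1999 ± 229 to 8413 ± 2021 TPM (adjusted p = 0.00518). Ifitm1, an interferon-induced membrane protein gene, rose from 5.96 ± 2.44 to 61.3 ± 29.3 TPM, Cd24a, a surface glycoprotein gene, from 14.6 ± 2.69 to 73.2 ± 10.9, and Il1r1, the signalling receptor of IL-1, from 1.14 ± 0.235 to 4.83 ± 0.95. Il24 rose by 1.45 ± 0.20, Dcn by 1.76 ± 0.31 and Iltifb by 2.24 ± 0.39. Il22, a near copy of Iltifb, was at 277 ± 24.2 TPM in GFPpos and 95.4 ± 14.7 in GFPneg and did not pass (adjusted p = 0.404). Its log2 change was 1.54, and 1.42 to 1.64 with 1 of the 6 libraries left out. The p-value uses 1 spread for all groups, so it does not show that Il22 was alike in these 6 libraries. The rows TDTOMATO and ICRE rose too, to 148 ± 36.4 and 9.13 ± 3.03 TPM.

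The genes that fell in GFPpos cells of IL-1b+IL-6+IL-23 included those of the costimulatory receptors Tnfrsf4 (730 ± 113 to 360 ± 36.2 TPM) and Tnfrsf18 (422 ± 54.3 to 210 ± 36.6 TPM; adjusted p = 0.00331 each). Ccr7, the homing receptor of naive and central memory cells, fell by 1.03 ± 0.18 and the cytotoxic granule gene Gzmb by 1.69 ± 0.35. The chaperone gene Hspa1a fell by 1.67 ± 0.27, Nrn1 by 1.43 ± 0.24, Ms4a4b by 1.72 ± 0.35 and the histone gene Hist1h2ab by 3.31 ± 0.65. Of the 15 tested genes of the Th17 program 3 rose (Il17a, Il17f and Il1r1) and 6 when adjusted over the list alone, with a median of 0.68 (camera adjusted p = 2.01e-07, and adjusted p = 0.0802 with an estimated correlation). Heat shock genes had a median of -0.39, with 1 of 7 falling over all genes and 5 adjusted over the list alone (adjusted p = 7.69e-08, and adjusted p = 0.0801 with an estimated correlation). Cytotoxic and natural killer receptor genes had a median of -0.28 with 1 of 8 falling, and 2 over the list alone (0.00252, and adjusted p = 0.191 with an estimated correlation). Interferon-stimulated genes (median -0.29; adjusted p = 1.35e-05) and proliferation genes (median -0.17; adjusted p = 0.00217) had no member passing either way, and lost the call with an estimated correlation (adjusted p = 0.169 and 0.444). Medians above 0 were found for cholesterol synthesis genes (0.24, adjusted p = 0.00666), with 3 of 20 rising adjusted over the list alone, for cytokine receptor genes (0.23, 0.0244), with 1 of 19 rising and 3 adjusted over the list alone, and for glycolysis genes (0.18, 0.013) with none. With an estimated correlation these 3 had adjusted p = 0.58, 0.573 and 0.64.

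Over all genes 41 differed in IL-1b+IL-6+IL-23, 33 higher and 8 lower in GFPpos, and 25 higher and 13 lower with median-ratio scaling, under which Ms4a4b and Hist1h2ab (adjusted p = 0.0825 and 0.0758) and the glycolysis list (median 0.112, adjusted p = 0.0714) were not called. Without GFPpos replicate 3 there were 17 genes, without GFPneg replicate 1 there were 20, and without GFPneg replicate 2, GFPpos replicate 2, GFPneg replicate 3 or GFPpos replicate 1 there were 23, 23, 27 and 27. Il17a, Il17f, Il1r1, Il24, Ifitm1, Cd24a, Tnfrsf4, Tnfrsf18 and TDTOMATO were called in each of these 6 fits. Dcn, Gzmb, Gstt3 and Dgat1 lost the call in all 6, Ms4a4b in 5, Iltifb, Ccr7 and Hist1h2ab in 4, Hspa1a in 3, Nrn1 in 2, and ICRE and Mt1 in 1. With all 21 libraries limma called 0 genes, with 79 at an unadjusted p under 0.05, and with 18 libraries 2. All 6 libraries of this comparison are among the 16, so the folds of both fits were the same and the spread was not.

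In TGFb+IL-6, the single GFPpos library among the 16 differed from 2 GFPneg libraries in part by genes seen above. Ifitm1 was at 39.5 against 1.21 ± 0.481 TPM, a rise of 4.21 ± 0.54 (n = 1 and 2; adjusted p = 0.00809), and Cd24a at 11.5 against 0.695 ± 0.983 (adjusted p = 0.0121). TDTOMATO was at 404 against 50.7 ± 2.74 TPM and ICRE at 17.1 against 1.55 ± 1.51 (adjusted p = 0.0389 each). Gstt3 rose by 2.02 ± 0.30, Serpine2 by 1.99 ± 0.40, Rabl2 by 2.56 ± 0.48, Zkscan14 by 2.26 ± 0.42 and Hspa1a by 2.97 ± 0.41. Hmgn2 fell by 1.35 ± 0.26, Hmgb2 by 1.21 ± 0.25, the decoy receptor gene Il1r2 by 2.00 ± 0.37, the mitochondrial leucyl-tRNA synthetase gene Lars2 by 3.77 ± 0.53 and H2-Q9 by 3.90 ± 0.68. Il17a (876 against 240 ± 29.3 TPM; adjusted p = 0.116) and Il17f (9497 against 4148 ± 843; adjusted p = 0.211) did not pass.

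The left-out GFPpos replicate 2 of TGFb+IL-6 shared some of these differences. It had Ifitm1 at 30.5 and H2-Q9 at 2.35 TPM, but Hspa1a at 5.16, Lars2 at 286, TDTOMATO at 19.9 and Il17a at 69.7 TPM. Cd24a, at 1.57 TPM, lay near the GFPneg level given above and not near that of GFPpos replicate 1. Replicate 3 had each of these 7 listed at 0. Among the lists, proliferation genes had a median of -0.44, and -0.915 with median-ratio scaling, with no member passing either way (camera adjusted p = 5.8e-09, and adjusted p = 0.169 with an estimated correlation). Medians above 0 were found for the Th17 program (0.97, with 0 of 15 passing and 6 rising adjusted over the list alone; adjusted p = 0.0244), co-inhibitory receptors and regulators (0.91, with 0 of 9 and 3; 0.0134) and cholesterol synthesis genes (0.65, with 0 of 20 and 0; 0.00891). With median-ratio scaling these medians were 0.496, 0.479 and 0.206. With an estimated correlation the lists had adjusted p = 0.426, 0.423 and 0.584, and the cholesterol list was not called with median-ratio scaling (adjusted p = 0.0963). Over all genes 31 differed, 25 higher and 6 lower, and 7 higher and 12 lower with median-ratio scaling, which moved the median of all genes from 0.368 to 0. ICRE, Serpine2, Rabl2 and Zkscan14 were not called with it (adjusted p = 0.0568 and, for the other 3, 0.0549). Without GFPneg replicate 1 or 2 there were 8 genes each, and Ifitm1, Hspa1a and Lars2 were called both times, while the other 15 rows named in this text as different lost the call in 1 or both. With all 21 libraries limma called 0 genes, with 284 at an unadjusted p under 0.05, and with 18 libraries 1.

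The calls of the 3 GFP comparisons, which share no library, were set against each other. All 3 use the same estimate of the spread for a gene, so a gene of low spread is favoured in each. The expected number and exact p-value below assume independent lists and genes, and so do not measure chance. Il23r and the reporter row were left out of the shared calls, since the sort fixes them. Cd24a, Dgat1, Gstt3 and Ifitm1, and the undescribed rows TDTOMATO and ICRE, were higher in GFPpos cells of both IL-1b+IL-6+IL-23 and TGFb+IL-6. Of the 6 only Ifitm1 was called in every fit of both comparisons with 1 library left out. Gstt3 and Dgat1 lost the IL-1b+IL-6+IL-23 call in 6 of 6 such fits and ICRE in 1, and TDTOMATO lost the TGFb+IL-6 call in 2 of 2 and Cd24a, ICRE, Gstt3 and Dgat1 in 1, so the shared number rests on single libraries. IL-12+IL-21 shared Mt1, a metallothionein gene, with IL-1b+IL-6+IL-23, and no higher gene with TGFb+IL-6. Mt1 was called in neither culture with median-ratio scaling (adjusted p = 0.313 and 0.131), and with 1 library left out it lost the call in 5 of 5 and 1 of 6 fits. Hmgb2, Hmgn2 and Ptma were lower in GFPpos cells of both IL-12+IL-21 and TGFb+IL-6 (expected 0.0025, exact p = 5.44e-10), though Ptma changed by 2.09 in TGFb+IL-6 with 21 libraries (adjusted p = 1). All 3 lost the TGFb+IL-6 call without either GFPneg library, which leaves 0 shared, and lost the IL-12+IL-21 call in 2, 4 and 5 of 5 fits. Under median-ratio scaling Inpp5b took the place of ICRE, and Ncl that of Ptma, both named after their values were seen, and no higher gene was shared by IL-12+IL-21 with either other culture. Lower genes shared by IL-12+IL-21 and IL-1b+IL-6+IL-23, or by the latter and TGFb+IL-6, numbered 0. In IL-12+IL-21 Cd24a changed by 1.70 ± 0.34 (adjusted p = 0.0643) and Ifitm1 by 1.56 ± 0.40 (adjusted p = 0.107), and the difference from the effect in IL-1b+IL-6+IL-23 had adjusted p = 0.992 and 0.871, and from that in TGFb+IL-6 0.995 and 0.797. Across genes, which are not independent replicates, the Pearson correlation of the GFP folds was 0.308, 0.278 and 0.102. With all 21 libraries no gene was shared, as limma called 0 genes in 2 of the comparisons. The GFP effect differed between IL-12+IL-21 and IL-1b+IL-6+IL-23 for 0 genes with 21 libraries (96 at an unadjusted p under 0.05) and for 0 with 16 (474), between IL-12+IL-21 and TGFb+IL-6 for 0 (160) and 1, and between IL-1b+IL-6+IL-23 and TGFb+IL-6 for 0 (96) and 8.

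In GFPneg cells, adding IL-21 to IL-12 went with less transcript of Th1 effector genes. GFPpos cells had been sorted out of IL-12+IL-21, and no GFPpos sample of IL-12 alone exists here. An effect of IL-21 and one of this sorting can therefore not be told apart in general. For Ifng, the GFPpos cells of IL-12+IL-21, at 328 ± 111 TPM, also lay below IL-12 GFPneg. Ifng fell by 2.88 ± 0.37, from 1297 ± 249 to 181 ± 70.1 TPM (n = 2 and 2; adjusted p = 0.00101), and the chemokine genes Ccl3 and Ccl4 fell by 2.84 ± 0.52 and 2.92 ± 0.35. Gzmb fell from 400 ± 155 to 32.6 ± 20.3 TPM (adjusted p = 0.000762), Il2 from 1061 ± 94.4 to 174 ± 135, Il10 from 6.58 ± 1.87 to 0.765 ± 0.0212 and Il17f from 16 ± 10 to 1.15 ± 0.785. Cd83 fell by 2.61 ± 0.38, Lad1 by 2.50 ± 0.32, Ccl1 by 2.98 ± 0.51, Irf8 by 2.17 ± 0.44, Serpinb9 by 1.53 ± 0.25 and Batf by 0.98 ± 0.20. Tbx21 was at 51.8 ± 26.8 and 64.5 ± 21 TPM (adjusted p = 0.847). Il21 itself rose by 2.03 ± 0.40, from 11 ± 1.79 to 47.9 ± 5.97 TPM, and Cd74, the invariant chain of class II molecules, from 42.2 ± 19.5 to 280 ± 27.4 TPM. The interferon-stimulated gene Isg15 rose by 2.11 ± 0.25 and the chemokine gene Cxcl10 by 2.25 ± 0.48, as did Phf11a (2.02 ± 0.35), Gmfg (3.12 ± 0.31), Serpinf1 (2.69 ± 0.33), Lum (2.68 ± 0.36) and Gap43 (3.16 ± 0.52). Klrd1 rose to 2.76 ± 0.368 TPM from libraries listed at 0. Il23r was at 4.7 ± 2.35 with IL-21 and 0.75 ± 1.06 TPM without (adjusted p = 0.0592).

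Of the 14 tested genes of the Th1 program 3 fell with IL-21 and 6 when adjusted over the list alone, with a median of -0.435 (camera adjusted p = 0.000749, and adjusted p = 0.237 with an estimated correlation). The pathogenic Th17 signature had 3 of 17 falling, Gzmb, Ccl3 and Ccl4, and 1 rising and 5 falling adjusted over the list alone (median -0.45; adjusted p = 0.0293, and adjusted p = 0.511 with an estimated correlation). Interferon-stimulated genes had 1 of 17 rising and 5 adjusted over the list alone (median 0.37; adjusted p = 3.57e-05, and adjusted p = 0.177 with an estimated correlation). Over all genes 73 differed, 30 higher and 43 lower with IL-21, and 38 higher and 23 lower with median-ratio scaling, which ended the call of Batf (adjusted p = 0.0735) and moved the median of all genes from -0.0888 to 0.0144. With 1 of the 4 libraries compared left out, 1 group held a single library, and which genes were called changed with the library left out. Ifng, Ccl4, Gzmb, Il17f, Isg15, Cd74, Lum, Serpinf1, Gmfg and Lad1 were called with any 1 of the 4 libraries left out. Il21, Irf8, Batf, Cxcl10 and Klrd1 lost the call in all 4 of these fits, Il2, Il10, Serpinb9, Gap43 and Phf11a in 3, Ccl1 and Ccl3 in 2, and Cd83 in 1. With all 21 libraries 2 genes were called, both lower, Ccn4 and Dapl1, and Ifng changed by -0.55, Gzmb by 0.0036 and Serpinb9 by 0.78 (adjusted p = 1 each), so the last 2 were not lower there. The left-out IL-12 GFPneg replicate 1 had Ifng at 78.8 TPM and IL-12+IL-21 GFPneg replicate 3 at 1369.

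Between GFPpos cells of IL-12+IL-21 and of IL-1b+IL-6+IL-23, Il23r was at 30.8 ± 6.18 and 28.5 ± 9.12 TPM (n = 3 and 3; adjusted p = 0.905), and several cytokine genes differed widely. Ifng was at 328 ± 111 TPM against 0.1 ± 0.173, a rise of 8.18 ± 0.30 (adjusted p = 5.83e-11), and Tbx21 at 72.7 ± 42.5 against 1.17 ± 1.06. Il17f was at 4.96 ± 1.53 against 8413 ± 2021 TPM (-10.47 ± 0.30), Il17a at 1.16 ± 1.14 against 837 ± 316 and Il22 at 8.75 ± 7.67 against 277 ± 24.2. Higher in IL-12+IL-21 were also Nkg7, a cytotoxic granule gene (861 ± 164 against 14.8 ± 5.92 TPM), Plac8, Crabp2, Ccl3, Ccl4, Irf8, Calca and the lymphotoxin gene Lta, with log2 changes of 3.83 (Lta) to 6.88 (Plac8). Higher in IL-1b+IL-6+IL-23 were the IL-1 decoy receptor gene Il1r2 (181 ± 24.3 against 8.14 ± 2.58 TPM) and the IL-1 receptor antagonist gene Il1rn. So were Tff1, Upp1, Dcn, Ido1, Iltifb and Lum (828 ± 286 against 69.3 ± 27.8 TPM), and the row TDTOMATO, with log2 changes of -4.34 (Il1r2) to -3.15 (Dcn and Ido1). Il21 was at 62 ± 12.7 and 52.1 ± 32.9 TPM (adjusted p = 0.64).

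By list, 8 of 14 tested genes of the Th1 program rose in IL-12+IL-21 and none fell (10 adjusted over the list alone, median 1.90, camera adjusted p = 1.38e-15). Of the Th17 program 9 of 15 fell and none rose (9 adjusted over the list alone, median -1.81, adjusted p = 3.72e-20). Cytotoxic and natural killer receptor genes had 6 of 8 rising, among them Serpinb9 at 111 ± 16.6 against 9.14 ± 1.83 TPM (6 adjusted over the list alone; median 1.86; 3.64e-10). These 3 calls held with an estimated correlation (adjusted p = 0.0215 each). Proliferation genes had 8 of 18 rising, such as Pcna (1.61 ± 0.17) and Plk1 (1.31 ± 0.22), and 13 adjusted over the list alone (median 0.72; adjusted p = 1.78e-08, and adjusted p = 0.169 with an estimated correlation). The pathogenic Th17 signature had 7 of 17 rising and 2 falling, 9 and 2 over the list alone (median 0.86; 0.000749, and adjusted p = 0.344 with an estimated correlation); members such as Tbx21, Ccl3 and Ccl4 are also Th1 genes. Interferon-stimulated genes went both ways, 2 of 17 rising, Gbp2 (1.99 ± 0.21) and Irf1 (2.28 ± 0.25), and 6 falling, such as Irf7 (-1.91 ± 0.31) and Rtp4 (-2.13 ± 0.28), or 4 and 9 adjusted over the list alone (median -0.72, adjusted p = 0.00111, and adjusted p = 0.306 with an estimated correlation). Co-inhibitory receptors and regulators had 2 of 9 rising, and 3 rising and 1 falling adjusted over the list alone (median 0.61, adjusted p = 0.0244). JAK-STAT feedback and STAT3 target genes had 1 of 14 rising and 2 falling either way (median -0.19, adjusted p = 0.0131), and Batf was at 122 ± 23.9 against 477 ± 32.4 TPM. Glycolysis genes had 1 of 16 rising, and 1 rising and 2 falling adjusted over the list alone (median -0.19, adjusted p = 0.00143). With an estimated correlation these had adjusted p = 0.432, 0.432 and 0.58. Median-ratio scaling moved the medians of the last 2 lists to -0.397 and -0.411.

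Other receptor genes with more transcript in IL-12+IL-21 than in IL-1b+IL-6+IL-23 were Il12rb2, the IL-12 receptor chain of Th1 cells (178 ± 14.2 against 23.6 ± 3.6 TPM), Il10ra (8.44 ± 1.53 against 0.123 ± 0.164), Cxcr1 (11.6 ± 1.78 against 0.117 ± 0.202) and Ccr7 (2025 ± 353 against 623 ± 169). In all 476 genes were called, 344 higher and 132 lower in IL-12+IL-21, and 255 higher and 227 lower with median-ratio scaling, which moved the median of all genes from 0.155 to -0.0179. Without IL-1b+IL-6+IL-23 GFPpos replicate 2 there were 317, and each gene named here as different was called with any 1 of the 6 libraries left out. With all 21 libraries, whose folds here are the same, 32 genes were called, 16 each way, and 7 higher and 15 lower with median-ratio scaling. Of the 32, 30 were among the 476 with the same sign. Il17a (adjusted p = 0.00566), Il17f (0.0131), Il22 (0.0196), Il1rn, Iltifb, Calca and Cxcr1 were among the 32, and Ifng (adjusted p = 0.0705) and Tbx21 (0.0822) were not.

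Between GFPpos cells of IL-12+IL-21 and of TGFb+IL-6, the latter a single library, Il23r was at 30.8 ± 6.18 and 3.57 TPM (n = 3 and 1; 2.78 ± 0.47; adjusted p = 0.00165). Ifng, at 328 ± 111 TPM in IL-12+IL-21, was listed at 0 in TGFb+IL-6, and Tbx21 was at 72.7 ± 42.5 and 0.83. Il17f was at 4.96 ± 1.53 and 9497 TPM, Il17a at 1.16 ± 1.14 and 876, and Ccl20, the ligand of the Th17 receptor CCR6, at 1.47 ± 2.55 and 926. Plac8, Nkg7, Penk, the proenkephalin gene (3412 ± 1061 and 41.9 TPM), Ermn and Serpinb9 rose in IL-12+IL-21 by 5.00 (Serpinb9) to 7.38 (Plac8). Ms4a4b, at 45.3 ± 12 TPM, was listed at 0 in TGFb+IL-6. Higher in TGFb+IL-6 were the cytokine gene Il9 (557 and 2.57 ± 1.96 TPM), the TGF-b-induced gene Tgfbi, Aqp3, Ltb4r1, Tmem176a and Tmem176b, with log2 changes of -7.42 (Il9) to -5.10 (Aqp3 and Tgfbi). Maf, a regulator of IL-10, was at 2.55 ± 1.36 and 16.7 TPM (adjusted p = 0.00535) and Il10 at 0.773 ± 0.722 and 4.86 TPM (adjusted p = 0.0193).

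In this comparison 10 of 14 tested genes of the Th1 program rose and 1 fell, and 13 and 1 adjusted over the list alone (median 2.53, camera adjusted p = 1.18e-14). Of the Th17 program 10 of 15 fell, and 1 rose and 10 fell adjusted over the list alone (median -2.40, adjusted p = 7.15e-17). Both calls held with an estimated correlation (adjusted p = 0.0215 each). Interferon-stimulated genes had 6 of 17 rising, such as Gbp2 (239 ± 34.3 and 32.8 TPM) and Isg15 (68.9 ± 4.03 and 12.2 TPM), and 9 adjusted over the list alone (median 0.81; 7.69e-08, and adjusted p = 0.0874 with an estimated correlation). The pathogenic Th17 signature had 9 of 17 rising, Lag3 among them (2.53 ± 0.34), and 12 over the list alone (median 1.59; 1.34e-07), and the non-pathogenic one 4 of 5 falling, Il9, Maf, Il10 and Il1rn, and 5 over the list alone (median -1.82; 3.09e-07). Naive and central memory genes had 5 of 11 rising, 6 over the list alone (median 0.96; 5.24e-05), and co-inhibitory receptors and regulators 1 rising and 5 of 9 falling, such as Pdpn (6.36 ± 3.14 and 232 TPM), 1 and 6 over the list alone (median -1.71; 0.000216). With an estimated correlation these 4 had adjusted p = 0.15, 0.0761, 0.15 and 0.202. Proliferation genes had 1 of 18 falling, 3 over the list alone (median -0.78; 7.03e-07), and the regulatory T cell program 2 of 11 falling, 5 over the list alone (median -0.42; 0.0263), with adjusted p = 0.231 and 0.46 with an estimated correlation.

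With 16 libraries 471 genes differed between IL-12+IL-21 and TGFb+IL-6, 300 higher and 171 lower in IL-12+IL-21, and 290 higher and 231 lower with median-ratio scaling. There were 327 to 492 with 1 of the 3 IL-12+IL-21 libraries left out, each gene named here as different among them. The single TGFb+IL-6 GFPpos library was in each of these fits, so they cannot test what rests on it. The fit of 21 libraries called 53, of which 52 were higher and 38 shared. Ms4a4b, Ermn, Calca (21 ± 5.71 against 0.72 TPM) and Cxcl10 (24.6 ± 9.7 against 2.16 TPM) were among the 53. Quantile scaling gave 27 higher and 21 lower and moved the median of all genes from 1.22 to -0.0189. In the left-out TGFb+IL-6 GFPpos replicate 2, Il17f was at 323, Il17a at 69.7, Ccl20 at 141, Il9 at 834, Aqp3 at 8.54 and Maf at 2.95 TPM, and Ifng and Il10 were listed at 0.

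Between GFPpos cells of IL-1b+IL-6+IL-23 and TGFb+IL-6, Il17a (837 ± 316 and 876 TPM; n = 3 and 1; adjusted p = 0.924) and Il17f (8413 ± 2021 and 9497 TPM; adjusted p = 0.857) did not pass. Il22 was at 277 ± 24.2 and 8.23 TPM (4.91 ± 0.77; adjusted p = 0.000908) and Il23r at 28.5 ± 9.12 and 3.57 (2.65 ± 0.47; adjusted p = 0.00253). Il1r2 (181 ± 24.3 and 0.85 TPM), Lum (828 ± 286 and 6.01 TPM), Pdzk1ip1, Ermn, Stra6 and Dcn rose in IL-1b+IL-6+IL-23 by 3.82 (Dcn) to 6.83 (Lum), and Tff1 (19.5 ± 5.36 TPM) and the tryptophan-degrading enzyme gene Ido1 (19.9 ± 9.72 TPM) were listed at 0 in TGFb+IL-6. Higher in TGFb+IL-6 were Ccl20 (926 and 0.573 ± 0.539 TPM), Ctla2a (1441 and 22.3 ± 1.99 TPM), its copy Ctla2b, Il9, Aqp3, Pdpn, Tmem176a, Tmem176b, Tgfbi and Ctsw, with log2 changes of -9.27 (Ccl20) to -4.81 (Ctsw). Maf was at 1.28 ± 0.461 and 16.7 TPM (adjusted p = 0.000936) and Il10 at 0.0967 ± 0.167 and 4.86 TPM (adjusted p = 0.00207).

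Interferon-stimulated genes rose together in IL-1b+IL-6+IL-23, 10 of 17 over all genes and 12 adjusted over the list alone (median 1.40, camera adjusted p = 2.15e-14, and adjusted p = 0.0265 with an estimated correlation). Among them were Isg15 (115 ± 9.11 and 12.2 TPM) and Irf7 (39.8 ± 8.88 and 5.31 TPM), while Ifit1, at 14.4 ± 0.378 TPM, was listed at 0 in TGFb+IL-6. Proliferation genes had 13 of 18 falling and 17 adjusted over the list alone (median -1.48; 3.91e-16, and adjusted p = 0.0692 with an estimated correlation). Co-inhibitory receptors and regulators had 1 of 9 rising and 6 falling, and 2 and 6 adjusted over the list alone (median -2.43, adjusted p = 1.11e-05). The non-pathogenic Th17 signature had 1 of 5 rising and 4 falling either way (median -2.43, adjusted p = 0.0109). The regulatory T cell program had 2 of 11 rising and 4 falling, and 2 and 7 adjusted over the list alone (median -1.16, adjusted p = 0.00252). With an estimated correlation these had adjusted p = 0.154, 0.344 and 0.345. Naive and central memory genes had 4 of 11 rising, such as the transcription factor genes Id3 (138 ± 19.2 and 11.6 TPM) and Tcf7 (67.8 ± 5.03 and 16.5 TPM), and 6 rising and 1 falling over the list alone (median 0.98; 0.000446, and adjusted p = 0.178 with an estimated correlation). The Th17 program had 3 of 15 rising, Batf among them (477 ± 32.4 and 80.8 TPM), and 5 falling (median -0.21), and its test did not pass.

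With 16 libraries 517 genes differed between IL-1b+IL-6+IL-23 and TGFb+IL-6, 227 higher and 290 lower in IL-1b+IL-6+IL-23. Median-ratio scaling turned the larger direction, with 343 higher and 296 lower. There were 364 to 405 with 1 of its 3 libraries left out, each gene named here as different among them. As the single TGFb+IL-6 GFPpos library could not be left out, these fits cannot test what rests on it. In the fit of 21 libraries there were 31, of which 30 were higher and 26 shared. Il1r2 (adjusted p = 0.000249), Il22 (0.000556), Ido1 (5.33e-06), Tff1, Dcn, Pdzk1ip1, Ifit1 and Ctsw were among the 31. Quantile scaling gave 35 higher and 29 lower and moved the median of all genes from 1.04 to -0.0337. In the left-out TGFb+IL-6 GFPpos replicate 2, Il22 was at 0.69, Lum at 0.17, Ccl20 at 141, Ctla2a at 572 and Pdpn at 124 TPM, while Il1r2 was listed at 0. It differed from the single library among the 16 in Il17a (69.7), Il17f (323), Maf (2.95 TPM) and Il10, listed at 0. In replicate 3 Lum was at 179 TPM.

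**Figure D3:**
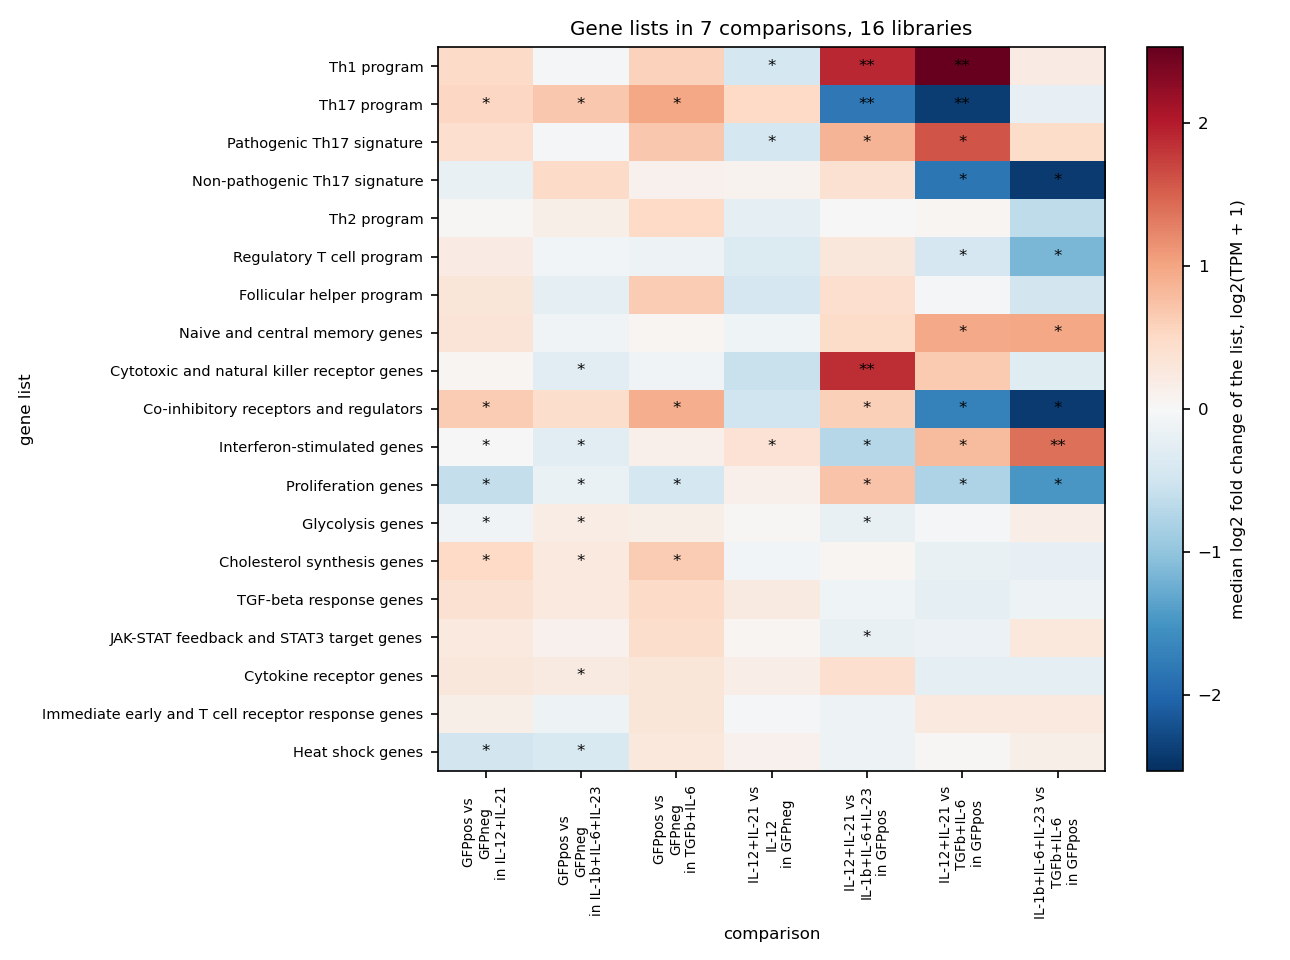
Median log2 fold change of the members (colour) of 19 gene lists (y axis) in the 7 comparisons (x axis), from 16 libraries. One asterisk marks a camera adjusted p under 0.05 at the preset correlation, and 2 asterisks also with an estimated correlation, as for the Th1 program (1.90) and the Th17 program (-1.81) between GFPpos cells of IL-12+IL-21 and IL-1b+IL-6+IL-23.

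Of 161 list tests 47 passed with 16 libraries and 6 of them also with an estimated correlation. With 21 libraries 27 and 2 did. In the 47 the median and mean of the members had the sign of the test. In the 27 the median went against it 5 times and the mean 7 times: glycolysis, interferon-stimulated and proliferation genes in the GFP comparison of IL-12+IL-21 tested lower with medians of 0.017, 0.136 and 0.741, where the median of all genes was 0.938. Co-inhibitory receptors and regulators between IL-12+IL-21 and TGFb+IL-6, and proliferation genes between IL-1b+IL-6+IL-23 and TGFb+IL-6, tested lower with medians of 0.162 and 0.746. Between the last pair the Th1 program (median -0.03, mean 0.04) and co-inhibitory receptors and regulators (median -0.73, mean 0.01) tested lower with median and mean apart.

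Other lists passed in none of the 7 comparisons with 16 libraries. Their smallest adjusted p was 0.0514 for the follicular helper program (9 tested; 0.0312 with median-ratio scaling, between GFPpos cells of IL-12+IL-21 and IL-1b+IL-6+IL-23), 0.0814 for TGF-beta response genes (7), 0.107 for the Th2 program (6) and 0.259 for immediate early and T cell receptor response genes (16). Few markers of other cells were high enough to be tested in these CD4 T cells. Ebf1, the 1 B cell marker tested (list adjusted p = 0.0621), was itself called between GFPpos cells of IL-1b+IL-6+IL-23 and TGFb+IL-6, at 19.8 ± 4.03 and 4.61 TPM (n = 3 and 1, 1.87 ± 0.46, adjusted p = 0.023). It lost the call in 2 of 3 fits with 1 library left out, and was not called with 21 libraries (adjusted p = 0.166). Cd68 and Xcr1 were the 2 myeloid and dendritic cell markers (list adjusted p = 0.0972). Cd8b1, the 1 CD8 T cell marker (0.145), was at 4.89 to 17.5 TPM in the 16 libraries beside Cd4 at 61.9 to 154. None of the 5 natural killer cell markers and 6 gamma-delta and innate-like T cell markers was high enough to be tested, and 0 of 9 mitochondrially encoded genes stood in the table. Foxp3 and Gata3, the regulators of regulatory and Th2 cells, had means of at most 1.62 and 6.97 TPM and passed in no comparison. Csf2 was listed at 0 in all 21 libraries, and Cd160 in all but IL-12+IL-21 GFPpos replicate 3, at 0.06 TPM. The row TRNE was at 181 ± 71.1 TPM in IL-12+IL-21 GFPpos and 436 ± 224 in IL-1b+IL-6+IL-23 GFPpos and listed at 0 in the TGFb+IL-6 GFPpos library. TRNQ was at 1654 ± 1114 TPM in IL-12+IL-21 GFPneg and listed at 0 in both IL-12 GFPneg libraries.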

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

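Of the tests in this part, the splits of the libraries were written before their result was seen; the splits without the sparse libraries and the tests on the libraries that stand apart, on ribosomal protein genes and on proliferation genes were chosen only after the result was seen.

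The effect of GFP status differed between cultures, by the test of the difference itself with 16 libraries, for 8 named genes. All of them rest on the single TGFb+IL-6 GFPpos library, and none passed with 21 libraries. The 8 calls between IL-1b+IL-6+IL-23 and TGFb+IL-6 became 3 without TGFb+IL-6 GFPneg replicate 1 or 2, and 5 without IL-1b+IL-6+IL-23 GFPpos replicate 2. The 1 call between IL-12+IL-21 and TGFb+IL-6 was lost in 5 of 7 such fits, those without either TGFb+IL-6 GFPneg library, IL-12+IL-21 GFPneg replicate 1 or 2, or GFPpos replicate 2. Hspa1a was lower in GFPpos cells of IL-1b+IL-6+IL-23 and higher in that library, a difference of -4.63 ± 0.49 (SE; adjusted p = 0.000754), and against IL-12+IL-21 the difference was -3.71 ± 0.51 (adjusted p = 0.0209). The left-out TGFb+IL-6 GFPpos replicate 2 had Hspa1a at 5.16 TPM, beside 7.1 and 5.04 in GFPneg replicates 1 and 2, and so did not share the rise. Between IL-1b+IL-6+IL-23 and TGFb+IL-6, the effect also differed for Cd9 (-2.41 ± 0.34, adjusted p = 0.0116), Crabp2 (-2.12 ± 0.33, 0.0186), Nrn1 (-2.95 ± 0.43, 0.0128), Penk (-3.02 ± 0.48, 0.0186), Tnfrsf18 (-1.44 ± 0.25, 0.0414), Il1r2 (2.91 ± 0.45, 0.0186) and Hist1h2be (3.83 ± 0.61, 0.0187).

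The rows TDTOMATO and ICRE carried signal that the labels leave undescribed. TDTOMATO had a mean of 148 TPM in IL-1b+IL-6+IL-23 GFPpos and stood at 404.1 in the TGFb+IL-6 GFPpos library, against 26.5 and 50.7 in the GFPneg cells of these cultures and group means of at most 8.56 in the IL-12 cultures (highest library 14.9). ICRE was at 9.13 and 17.1 TPM, against 0.98 and 1.55 in the GFPneg cells, and was listed at 0 in the IL-12 cultures among the 16 libraries. No explanation was tested.

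The library labelled TGFb+IL-6 GFPpos replicate 3 held transcripts of the IL-12 cultures. Ifng was at 989 TPM, Tbx21 at 143 and Il23r at 146, while Il17a and Il17f were listed at 0, and 17 of 35 genes typical of the IL-12 cultures lay above 0 against 1 of 22 typical of TGFb+IL-6 (Fisher's exact p = 0.000394). The chance of 17 or more at the sparseness of the library was 1.05e-09, 1.78e-11 and 8.86e-12 by the detection of 50, 200 and 500 genes of like TGFb+IL-6 level, which argues against a low depth of RNA from the labelled culture as the whole cause. A library of the same sparseness would hold 16.3 of the IL-12 genes if it came from an IL-12 culture and 10.1 of the others if it came from TGFb+IL-6, so RNA from an IL-12 culture, by carry-over or a wrong label, is a candidate explanation. For the library labelled TGFb+IL-6 GFPneg replicate 3, with Ifng at 3285, Plac8 at 6647 and Gzmb at 2727 TPM, the counts were 3 and 0 (exact p = 0.276) and the same 3 chances of as many were 0.0542, 0.00679 and 0.00448, all sought after the exact test was known, so whether low depth is the whole cause turns on the number of genes used; it and RNA from an IL-12 culture cannot be told apart. With 50 genes the expected number was 0.863 and could not fall below 0.686, so the chance of 0.0542 is raised by that floor. Ifng, 1 of the 3 genes above 0, was listed at 0 in the TGFb+IL-6 libraries among the 16. That speaks for RNA from an IL-12 culture without deciding it. The difference between the sets, 1.02 against -4.19 to -3.87 in those libraries, comes from the same 3 genes and adds no evidence. No biological explanation was tested, since the design gives none for single replicates.

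IL-12 GFPneg replicate 1 and TGFb+IL-6 GFPpos replicate 2 had a high share of ribosomal protein genes, and correlated with each other at 0.92. The mean log2 level of the IL-12 genes minus that of the TGFb+IL-6 genes was 3.57 and -2.21, against 4.41 to 5.59 in the IL-12 cultures and -4.19 to -3.87 in TGFb+IL-6 among the 16 libraries, which argues against RNA wholly from the other of these cultures, while a mixture and a label exchanged with any other culture were not tested. Among abundant genes other than ribosomal ones, those of at most 600 nt exceeded longer ones by 2.76 and 1.92 on the log2 scale. In 15 other libraries this difference was -0.272 to 0.35. The limit of 600 nt was set after the values by length had been seen. The rank correlation of the change with length was -0.123 and -0.111, inside the -0.184 to 0.173 of those 15. It covered less abundant genes too, and the ribosomal ones, so the 2 measures rest on unlike genes. Whether short transcripts in general are favoured stays open. Of the abundant ribosomal protein genes 35 of 83 and 38 of 82 rose, with medians of -0.332 and -0.0254, so the typical member did not carry the high share, and its difference from genes matched on length and level, 0.486 ± 0.274 and 0.357 ± 0.175 (SE), leaves open whether length is the whole cause. Partial degradation, the amount of RNA and other sources stay open and untested.

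Proliferation genes were lower on average in GFPpos cells of each culture with 16 libraries. The mean was -0.568 ± 0.0683, -0.195 ± 0.0545 and -0.37 ± 0.09 in IL-12+IL-21, IL-1b+IL-6+IL-23 and TGFb+IL-6. After a loess fit on length, GC content and level it was -0.805 ± 0.0702, -0.255 ± 0.0545 and -0.681 ± 0.0954. This argues against length, GC content and level as the whole cause of the members' place below other genes. The SEs are over genes, which are not independent. With median-ratio scaling the medians were -0.875, -0.239 and -0.915. That scaling lowered the median of all genes, from 0.244, 0.0742 and 0.368 to 0.0132, 0.0216 and 0. It could thus only lower the list, and decides nothing about scaling as a cause. The loess fit also took out the shift of all genes, so it does not test a fall below 0, and the larger fall after it is no added evidence. By library the mean level was 4.11 to 4.53 in GFPpos and 4.70 to 4.97 in GFPneg, 3.27 to 3.60 and 3.57 to 3.76, which overlap, and 4.99 in 1 GFPpos library and 5.24 to 5.47, and with an estimated correlation between genes the adjusted p was 0.0676, 0.444 and 0.169, and with 21 libraries the median in IL-12+IL-21 was 0.741. Slower division of cells with an active reporter is a hypothesis from the 16-library values and was not tested. The lower values were found and checked on the same data.

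Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. With 21 libraries, the real split of IL-12+IL-21 by GFP status called 6 genes and the highest other 3, so 1 of the 10 reached the real value. For IL-1b+IL-6+IL-23 the real value was 0 and the highest other 3, and for TGFb+IL-6 they were 0 and 5644, so all 10 reached it; the split with 5644 points to a structure of the samples. It set TGFb+IL-6 GFPneg replicate 3 and GFPpos replicates 2 and 3, which stand apart, against the other 3, and without the sparse libraries it called 45 genes and the real split 1. Between IL-12+IL-21 and IL-12 the real value was 2 and the highest other 7, with 3 splits reaching it. Among GFPpos cells the real values were 32, 53 and 31 and the highest others 1, 6 and 10 for IL-12+IL-21 against IL-1b+IL-6+IL-23, IL-12+IL-21 against TGFb+IL-6 and IL-1b+IL-6+IL-23 against TGFb+IL-6, with 1 split each reaching the real value. With 16 libraries, IL-1b+IL-6+IL-23 by GFP status had 41 and 3, and IL-12+IL-21 against IL-1b+IL-6+IL-23 had 476 and 1. For the 3 differences of the GFP effect the real value was 0, which all 100 of 100 drawn splits reached, with highest others of 5, 5378 and 56. Any split reaches a value of 0, so these shares decide nothing. The same holds for IL-1b+IL-6+IL-23 and TGFb+IL-6 by GFP status with 21 libraries.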

How the results depend on the processing

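The fits of 18 and 16 libraries were chosen only after the data were seen; all other alternatives in this part were planned. Numbers of called genes are given in the order of GFPpos against GFPneg in IL-12+IL-21, in IL-1b+IL-6+IL-23 and in TGFb+IL-6, IL-12+IL-21 against IL-12, IL-12+IL-21 against IL-1b+IL-6+IL-23, IL-12+IL-21 against TGFb+IL-6, and IL-1b+IL-6+IL-23 against TGFb+IL-6, and the 3 differences of the GFP effect follow in the order used above. With 21 libraries they were 6, 0, 0, 2, 32, 53 and 31, then 0, 0 and 0. Without the 3 sparse libraries they were 0, 2, 1, 1, 68, 120 and 100, and without 5 libraries 15, 41, 31, 73, 476, 471 and 517, then 0, 1 and 8. The latter with median-ratio scaling gave 38, 19, 61, 482, 521 and 639 from the second comparison on, then 2 and 11 for the last 2 differences. Array weights gave 1658, 77, 8233, 2232, 719, 8526 and 8516, then 111, 7417 and 6832. The largest weight, 461, went to TGFb+IL-6 GFPpos replicate 2, which is not among the 16 libraries, and replicate 1 had 0.0569, so these counts and the signs that turn with them may rest largely on that library. Only the libraries compared gave 2, 32, 1, 5 and 473 in the first 5, 2 in the last, and 2 and 3 for the last 2 differences. The cause of these shifts was not tested, except that the spread falls with the libraries left out.

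Single settings moved further counts. A pseudocount of 0.1 gave 17 for GFP in TGFb+IL-6, 13, 26 and 6 among GFPpos cells, and 1 and 1 for the last 2 differences, and a pseudocount of 5 gave 4 for GFP in IL-1b+IL-6+IL-23, 1 for IL-12+IL-21 against IL-12 and 56 for the last comparison. No filter gave 8, 58 and 88 for GFP in IL-1b+IL-6+IL-23, IL-12+IL-21 against it, and the last comparison, and a minimum of 5 TPM gave 1, 11, 11 and 12 from IL-12+IL-21 against IL-12 on. Quantile scaling gave 0 and 0 in the comparisons within IL-12 cultures, where limma had 406 and 212 genes at an unadjusted p under 0.05 before scaling, and 64 in the last. Median-ratio scaling of 21 libraries gave 1 for IL-12+IL-21 against IL-12 and 27 for IL-12+IL-21 against TGFb+IL-6. Without a trend the numbers were 0, 0, 12 and 9 for GFP in IL-12+IL-21, IL-12+IL-21 against IL-12, and IL-12+IL-21 against the other 2 cultures. With each library left out in turn the ranges were 2 to 8, 0 to 4, 0 to 26, 0 to 12, 16 to 25, 18 to 45 and 16 to 33, then 0 to 4, 0 to 2 and 0 to 1. List tests past the threshold were 27, and 13 without the filter, 43 with 18 libraries, 47 with 16, 51 with 16 and median-ratio scaling and 2 with an estimated correlation. Genes shared between GFP comparisons, with Il23r and the reporter row counted, were 0, and 1 with a pseudocount of 0.1 or 18 libraries, 14 with 16 and 10 with 16 and median-ratio scaling.

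Whether replicate numbers pair the samples stays open. Correlations of deviations between same-numbered libraries ran from -0.201 to 0.394 over 21 pairs and from -0.0861 to 0.156 over 9 pairs of the 16. Low correlations over all genes cannot exclude a pairing. The block raised the number of calls with 16 libraries, for GFP in IL-1b+IL-6+IL-23 from 41 to 51. With the replicate number as a block, 21 libraries gave 1 gene for IL-12+IL-21 against IL-12. The block with 16 libraries gave 23, 51, 39, 135, 560, 476 and 518 genes, then 1, 1 and 11, with 46 list tests, 18 shared genes and Il23r at 2.49 and 1.85 for GFP in IL-12+IL-21 and IL-1b+IL-6+IL-23. Under that block Hmgn2 was at -1.30, Ifng at 0.78 and Csf3r at -0.67 for GFP in IL-12+IL-21, Il17f at 1.19, Ptma at -0.84, Ncl at -0.77 and Inpp5b at 1.71 for GFP in TGFb+IL-6, Gzmb at -3.49 and Serpinb9 at -1.46 for IL-12+IL-21 against IL-12, Il21 at -0.0816 for IL-12+IL-21 against TGFb+IL-6, and Il17a at -0.51 and Il17f at -0.17 for the last comparison, each of the other sign than with 21 libraries and no block.

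Il23r by GFP status passed with array weights at 2.13, 1.85 and 0.63 in the 3 cultures, and at 2.64 for IL-12+IL-21 against IL-12. With 16 libraries it passed at 2.52 and 1.85, with median-ratio scaling at 2.25 and 1.79, and at 1.88 for IL-12+IL-21 against IL-12, and with only the libraries compared at 1.85 in IL-1b+IL-6+IL-23. With 1 of the 16 libraries left out, Il23r by GFP status lost the call in 3 of 5 fits in IL-12+IL-21 and in 5 of 6 in IL-1b+IL-6+IL-23. Of 184 named gene results 152 changed sign nowhere and 32 did in some setting.

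With 16 libraries the sign differed from that with 21 for Hmgn2 (-1.28), Ifng (0.86) and Csf3r (-0.73) by GFP in IL-12+IL-21, Il17f (1.21), Ptma (-0.86), Ncl (-0.73) and Inpp5b (1.76) by GFP in TGFb+IL-6, Gzmb (-3.67), Serpinb9 (-1.53) and Tbx21 (-0.37) for IL-12+IL-21 against IL-12, Il21 (-0.0413) for IL-12+IL-21 against TGFb+IL-6, and Il17a (-0.13) and Il17f (-0.21) for the last comparison. Median-ratio scaling of these gave -1.57, 0.57, -0.95, 0.73, -1.34, -1.20, 1.30, -3.53, -1.40, -0.23, -0.15, -0.0216 and -0.0985 in that order, and -0.0796 for Il23r between IL-12+IL-21 and IL-1b+IL-6+IL-23. With 18 libraries Hmgn2 was at -1.28, Ifng at 0.86, Csf3r at -0.73, Gzmb at -2.04, Ptma at -1.85 and Ncl at -1.615. Quantile scaling gave Hmgn2 -0.465, Tbx21 -0.20 and Csf3r -0.62 by GFP in IL-12+IL-21, Gzmb -0.59 against IL-12 and Il23r -0.0384 between IL-12+IL-21 and IL-1b+IL-6+IL-23. Gzmb was at -0.77 with median-ratio scaling of 21 libraries and at -0.00498 with a pseudocount of 5, where Csf3r was at -0.0156. Inpp5b by GFP in TGFb+IL-6 was at 0.0688 with median-ratio scaling of 21 libraries. A pseudocount of 0.1 gave Il10 0.54 and Maf 0.45 for IL-12+IL-21 against TGFb+IL-6.

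Array weights turned Hmgn2 (-1.29), Ifng (1.33), Tbx21 (-0.20) and Csf3r (-0.57) by GFP in IL-12+IL-21, and the reporter row (-0.0279), TDTOMATO (-1.25), Gstt3 (-0.46), Serpine2 (-1.93), Lars2 (0.17), Il17a (-1.87), Rabl2 (-0.35), Zkscan14 (-0.0447), Dgat1 (-0.0844), Ptma (-2.75) and Ncl (-2.29) by GFP in TGFb+IL-6. They also turned Gzmb (-4.48), Serpinb9 (-1.46) and Tbx21 (-0.0736) against IL-12, and Il10 against TGFb+IL-6 (0.55 for IL-12+IL-21 and 0.11 for IL-1b+IL-6+IL-23). Leaving out 1 of the 21 libraries in turn gave ranges across 0. By GFP in IL-12+IL-21 they were -1.28 to 2.09 for Hmgn2, -0.83 to 0.86 for Ifng, -0.28 to 0.47 for Tbx21 and -0.73 to 0.85 for Csf3r. By GFP in TGFb+IL-6 they were -0.27 to 1.44 for the reporter row, -1.60 to 2.73 for TDTOMATO, -0.56 to 2.33 for Hspa1a, -3.99 to 0.83 for Lars2, -2.60 to 2.69 for Il17a, -4.82 to 2.77 for Il17f, -0.0765 to 1.37 for Rabl2, -0.0164 to 1.52 for Zkscan14, -1.32 to 2.46 for Dgat1, -1.56 to 3.96 for Ptma, -0.73 to 2.35 for Ncl and -2.21 to 0.79 for Inpp5b. Against IL-12 they were -2.04 to 1.35 for Gzmb, -1.89 to 0.22 for Ifng, -1.64 to 0.53 for Irf8, -0.98 to 1.72 for Serpinb9 and -0.10 to 2.35 for Tbx21, and for Il23r between IL-12+IL-21 and IL-1b+IL-6+IL-23 -0.0364 to 0.37. For IL-12+IL-21 against TGFb+IL-6 they were -3.04 to 0.64 for Aqp3, -0.54 to 0.73 for Il10 and -1.32 to 0.75 for Maf, and for IL-1b+IL-6+IL-23 against TGFb+IL-6 -1.89 to 0.18 for Maf and -1.15 to 0.12 for Il10. As the values are TPM, the number of reads behind them is unknown, which limits what can be said of low genes.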
